A study of Sus scrofa with 4 samples.

How the data were processed

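The data are droplet single-cell RNA libraries, made with the 10x Genomics 3′ chemistry, from regenerated bone of Bama mini-pigs (Sus scrofa) aged 8 months. Per the labels' protocols, the tissue was digested with type I collagenase and red blood cells were lysed. There were 2 libraries of the 1797 peptide group and 2 of the control peptide group, 4 in all, and the groups follow the sample labels. Further control samples that the series describes were not analysed here. The labels do not state that the libraries of a group came from separate animals. The p-values of single genes and cell shares thus measure only the spread between these samples, which may be technical.

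The deposited values are raw UMI counts per gene and barcode in a filtered matrix, with 20648 genes. The counts were made with Cell Ranger 5.0.0 on the Sscrofa11.1 build per the submitters' processing notes, while version 7.0.1 stands in the matrices per the file headers. The other deposited files, of gene names and barcodes, hold text and no measurement. Each barcode in the matrices had at least 500 UMIs. Coordinates are from a RefSeq gene table of the same build, counted from 1.

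Barcodes with at least 200 genes and under 20% of counts in the 13 mitochondrial genes were kept. Scrublet, as implemented in scanpy 1.11.5 with an expected doublet rate of 0.1, called 1813 doublets, which were removed. This left 49122 cells. Counts were log-normalised, 2000 variable genes were chosen across libraries and 30 principal components were computed. Leiden clustering at resolution 1.0 on 15 neighbours, without integration of the libraries, gave 30 clusters with igraph 0.11.9. Cluster borders moved with the seed and with the last digits of the neighbour weights, so the linear algebra routines were fixed and the clustering was repeated with another seed, which left 99.14% of cells in the same class but did not part osteoclast-like from macrophage-like cells. A cluster was given a type only from fixed marker lists, and all type names used here mean clusters with the markers of that type (monocyte-like and so on). This gave 14 classes, and 9 clusters stayed unnamed. No type labels from the authors were used here.

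Raw counts were summed per library and class, since cells are not replicates. The 8 classes with at least 50 cells in every library, and the sum of all cells, were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM factors, filter on low counts, no covariate) with Benjamini-Hochberg adjustment within each fit. Genes were called at an adjusted p of 0.05. DESeq2 1.42.0 served as a second tool. Cell numbers per class were compared with the same edgeR test, with the total of kept cells as offset. The 22 gene lists, which cover bone, cartilage, immune, vessel and metabolic functions, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members. With the preset correlation camera compares the members of a list with the other genes, so its p rests mostly on the spread between genes. It says little about the spread between libraries. The same test was run with an estimated correlation, and fry was run as a further alternative. Where the p of a list is given with 1 library left out, the lowest p over the fits with a library left out stands beside it. The 21 marker lists were put to the same test to show transcripts of other cell types in each class. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so it was not used for single values. CPM values are scaled to the total count of the class in a library. Errors of CPM are the SD of 2 libraries, and errors of log2 fold changes are standard errors from edgeR.

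The lists, markers, tests, cell filters and most alternatives were chosen before the data were examined. So was the rule for named genes. It took up to 10 genes each way per comparison with adjusted p under 0.05, an absolute log2 fold change of at least 1 and both libraries of a group apart from both of the other. A total of 0 genes met it. It also took up to 4 members of each list described, and fixed genes in the osteoblast, macrophage, monocyte and neutrophil classes. Which of the called lists to describe was decided after the tests. The stromal or osteoblast class had 45 cells in its smallest library, below the minimum, and was fitted as an addition after the cell numbers were seen. Settings of the macrophage and neutrophil clusters, and the other clustering seed, were added after the clusters were seen. Interaction tests between classes were not among the tests fixed beforehand. The alternatives were other size factors, no filter on low counts, the replicate number as a block, each library left out, doublets kept, a stricter cell filter (500 genes, 10% mitochondrial), Leiden resolutions 0.5 and 2.0, and a denominator without neutrophil and erythroid cells.

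The tests were tested on simulated data for 4 of the fits, in 5 runs with 200 changed genes each. Changed genes were drawn from all but those with the lowest levels. In macrophages, with 12488 genes run, edgeR recovered 28.4% of genes changed 2-fold and 92.4% of those changed 4-fold, and 11.8% of its calls were false. In monocytes (11276 genes) the shares were 16% and 83.8% with 12.5% false, and in T cells (13230 genes) 35.2% and 91.2% with 10.4% false. In the sum of all cells (16500 genes) edgeR recovered 0.2% and 3.2%, and 41.4% of its few calls were false. DESeq2 recovered more, 50% and 96% in macrophages, with 17.8% false calls there, 15.9% in monocytes, 17.1% in T cells and 52.6% in the sum of all cells. Other software was R 4.3.3, Python 3.11.15, anndata 0.12.19, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.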

Results

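Single-cell transcriptomes were measured in regenerated bone of 8-month-old Bama mini-pigs, a small domestic pig breed. The series concerns the anabolic effect of peptides in bone regeneration, and its design sets a peptide called 1797 against a control peptide, with 2 libraries in each group. The 1797 libraries held 14496 and 13449 barcodes with 87844389 and 98758412 UMIs in total, and the control libraries 13982 and 12133 barcodes with 96410215 and 98294210 UMIs. After filtering, 12199 and 12722 cells of the 1797 libraries and 12732 and 11469 cells of the control libraries were kept. Median depth was 3867 and 3156.5 UMIs per kept cell in the 1797 libraries against 5345 and 4606 in the control libraries. Library 1 of the 1797 group also had the most barcodes under 200 genes (1159, against 55 to 309 in the others) and the highest median mitochondrial share (4.67%, against 2.84% to 3.00%). The libraries of a group differed from each other by far more than counting noise, with a chi-square per degree of freedom of 334.8 for the 1797 pair and 343.3 for the control pair.

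The first comparison asks whether the cell make-up of the regenerated tissue differed between the peptides. Blood and immune cells filled most of every library. Neutrophil-like cells made up 29.99% ± 16.5 of cells in the 1797 libraries and 26.2% ± 14.5 in the control libraries (SD, n = 2), T cell-like cells 20.1% ± 1.74 against 21.3% ± 6.56, and macrophage-like cells 8.68% ± 0.689 against 8.65% ± 1.72. Chondrocyte-like cells, which carry the collagen and proteoglycan genes of cartilage, were 37 and 14 cells in the 1797 libraries and 2 and 5 in the control libraries (0.206% ± 0.136 against 0.030% ± 0.020). NK or cytotoxic T-like cells were lower, at 6.82% ± 2.04 against 12.2% ± 5.68. Stromal or osteoblast-like cells, the bone-forming lineage, held 1.55% ± 1.70 and 1.43% ± 0.707, and bone-resorbing osteoclast-like cells 0.526% ± 0.223 and 0.308% ± 0.158.

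Of the 14 classes, 0 differed in share by edgeR at the adjusted threshold. The chondrocyte-like class, with a log2 ratio of 2.77 ± 1.01 (SE) and an edgeR adjusted p of 0.344, was the 1 class with an unadjusted p under 0.05. Its ratio stayed positive without each library, from 1.87 without 1797 library 1 to 3.63 without control library 2. NK or cytotoxic T-like cells had a log2 ratio of -0.84 with an edgeR adjusted p of 0.967, from -0.27 without control library 1 to -1.253 without control library 2, and the libraries of the groups overlapped. Shares also varied between libraries of 1 group: 1797 library 1 held 718 endothelial-like cells and library 2 held 76. Unnamed clusters took 10.7% ± 3.78 and 12.1% ± 0.984 of cells.

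**Figure D1:**
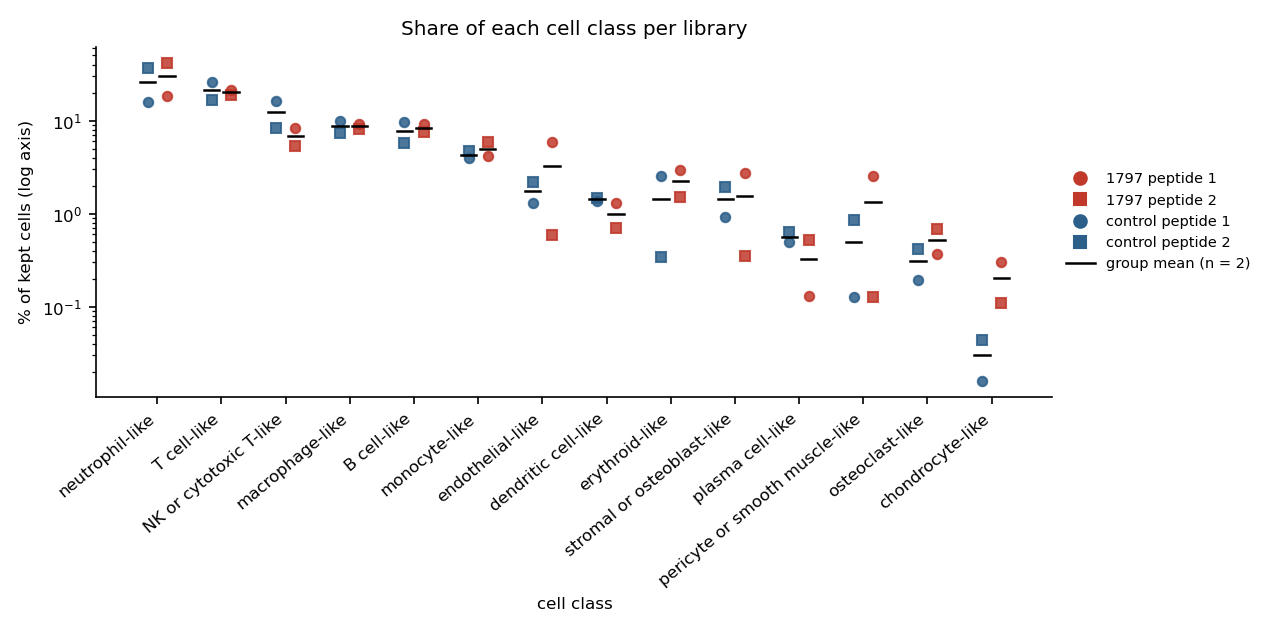
Percent of kept cells (log axis) in each of 14 cell classes, with circles for library 1 and squares for library 2 of the 1797 peptide (red) and control peptide (blue) groups and black bars for group means (n = 2). The groups overlap or lie close in most classes, and the chondrocyte-like class stands apart with means of 0.206% and 0.030%.

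The sum of all cells shows what differed in the tissue as a whole. Cartilage matrix genes were higher in the 1797 libraries, with 15 of 16 tested members higher and a median log2 fold change of 1.62. COMP, a cartilage matrix protein that binds collagen (chromosome 2, 59061409 to 59068951, Sscrofa11.1), stood at 19.1 ± 3.99 CPM against 1.54 ± 1.51. Its log2 fold change was 3.62 ± 0.89, and those of the collagen genes COL11A2 and COL9A3 and of the cartilage gene CNMD were 1.87 ± 0.53, 2.73 ± 0.80 and 3.07 ± 0.92. Genes of cytotoxic effectors, the killing machinery of NK and T cells, were lower in 15 of 15 members. GNLY, the membrane-lysing granulysin (chromosome 3, 59067327 to 59072034), was at 49.9 ± 5.58 against 107 ± 7.07 CPM, and CST7, CCL5 and TNFSF10 had log2 fold changes of -0.92, -0.83 and -0.75. Osteoclast function genes were higher in 15 of 16 members. They included the regulator NFATC1 (0.57 ± 0.19), the transporter gene SLC9B2 (0.91 ± 0.31), the proton pump subunit ATP6V0D2 (1.10 ± 0.41) and the integrin ITGB3 (0.85 ± 0.35).

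Each of these 3 lists was called by camera, at adjusted p of 1.73e-13 for cartilage matrix, 5.13e-11 for cytotoxic effectors and 7.33e-09 for osteoclast function. Each had an adjusted p of 0.645 with an estimated correlation. Both 1797 libraries lay beyond both control libraries for 10, 8 and 7 members. No single member passed edgeR, with 6, 2 and 2 at unadjusted p under 0.05 and 0 of each adjusted over the list alone. Cell shares moved the same way as the 3 lists, though none was called. They were 0.206% against 0.03% for chondrocyte-like, 6.82% against 12.2% for NK or cytotoxic T-like and 0.526% against 0.308% for osteoclast-like cells. The lists over all cells are thus not separate from the cell make-up. T cell markers, which share no member with these lists, were lower in 10 of 10 (median -0.44, camera adjusted p = 3.96e-05, and adjusted p = 0.671 with an estimated correlation). Control library 1 stood apart there, with a median log2 level of the T cell markers against the mean of the libraries of 0.567, against -0.104 in control library 2 and -0.187 and -0.174 in the 1797 libraries, and of the cytotoxic effectors of 0.612, against -0.023, -0.118 and -0.378. Interferon response genes were lower in 30 of 32 (median -0.29, camera adjusted p = 3.52e-06, and adjusted p = 0.695 with an estimated correlation). Without 1797 library 1 that camera adjusted p was 0.328, in a range from 4.4e-09 over the libraries left out in turn. Inflammatory cytokines and NF-kB targets were higher in 17 of 24 (median 0.36, camera adjusted p = 0.00656, and adjusted p = 0.879 with an estimated correlation), and without 1797 library 2 the list turned the other way at 0.285, while without control library 2 the p was 0.0503 (lowest 3.56e-08).

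Genes that make bone matrix and mineral were lower in 17 of 25 members over all cells (median -0.32), which camera did not call (adjusted p = 0.0534). That rested on 1797 library 2, as median log2 levels of the list against the mean of the libraries were 0.312 and -0.567 in the 1797 libraries and -0.082 and 0.239 in the controls. Angiogenesis genes were higher in 19 of 21 (median 0.38, camera adjusted p = 0.0544), and BMP and TGF-beta targets, the signals that drive bone formation, in 14 of 17 (median 0.33, camera adjusted p = 0.145). Both rested on 1797 library 1, with median levels of 1.036 and -0.709 against -0.627 and 0.371 for angiogenesis and of 0.527 and -0.363 against -0.283 and 0.111 for the BMP and TGF-beta targets. Endothelial-like cells followed the same order of libraries, with 718 and 76 cells against 164 and 250. At the level of single genes edgeR called 0 of 16652, with 265 (1.59%) at unadjusted p under 0.05, and DESeq2 called 19. In the 8 tested classes edgeR also called 0 genes in each, with 4997 of 94695 tests at unadjusted p under 0.05, and DESeq2 called 290. Chance alone gives a share near 0.05 at that threshold, which holds for the unadjusted counts of the classes below too. The other ways to split the 4 libraries into pairs gave 6865 and 4239 of 94695, so 4997 lay between them.

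Monocyte-like cells, a cluster led by IL1B itself, carried more transcripts of inflammatory cytokines and NF-kB targets in the 1797 libraries. Of 24 tested members 23 were higher, with a median log2 fold change of 0.53. CCL2, the chemokine that draws monocytes (chromosome 12, 40798109 to 40800013), stood at 399 ± 95.2 against 187 ± 16.6 CPM. CXCL8, which draws neutrophils (chromosome 8, 69932646 to 69935861), was at 3012 ± 113 against 1717 ± 83.7, the cytokine LIF (chromosome 14, 47221540 to 47239513) at 125 ± 2.61 against 70.3 ± 9.19, and CCL20 at 30.01 ± 1.56 against 14.2 ± 2.96. IL1B was at 1372 ± 97.3 against 872 ± 129 and TNF at 11.11 ± 5.75 against 5.42 ± 0.81 CPM. Levels of CXCL8, LIF, CCL20 and TNF in neutrophil-like cells of the 1797 libraries, at 13002.79, 190.63, 100.4 and 5.74 CPM, were above those in monocyte-like cells of the controls.

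The list was called by camera at an adjusted p of 1.87e-12, with an adjusted p of 0.314 with an estimated correlation. By edgeR 0 members passed over all genes and 8 passed adjusted over the list alone, with 12 at unadjusted p under 0.05, and both 1797 libraries lay above both control libraries for 16. Those 8, chosen by their p in this class, had a median log2 fold change of 0.818 here. Such a choice favours a larger median here, so the medians below do not rank the classes. Elsewhere the median of those measured was 0.598 in NK or cytotoxic T, 0.597 in neutrophil and 0.431 in endothelial-like cells. It was 0.389 in T, 0.285 in B, 0.222 in macrophage and 0.171 in dendritic cell-like cells. CXCL8 was higher in each tested class. For CCL2 the log2 fold change was 1.09 ± 0.22 (edgeR adjusted p = 0.635), for CXCL8 0.81 ± 0.17 (edgeR adjusted p = 0.635), and DESeq2 called both (adjusted p = 0.00382 and 0.00747). Osteoclast-regulating cytokines, an overlapping list that includes LIF, CCL2 and the macrophage growth factor CSF1 (62.9 ± 10.6 against 37.5 ± 5.45 CPM), had 5 of 9 members higher and a median of 0.39. Camera called it at an adjusted p of 0.0123, with an adjusted p of 0.679 with an estimated correlation and 3 members adjusted over the list alone by edgeR. That call rested on 1797 library 1 and control library 1, without which its camera adjusted p was 0.0614 and 0.215 (lowest 0.00126). Dissociation and immediate early stress genes were higher in these cells too, in 21 of 30 (median 0.27, camera adjusted p = 0.011, and adjusted p = 0.679 with an estimated correlation), with 0 members adjusted over the list alone by edgeR and 4 at unadjusted p under 0.05. Without 1797 library 1 and without control library 1 that camera adjusted p was 0.171 and 0.082, and at Leiden resolution 0.5 it was 0.102 (lowest over all alternatives 0.00104).

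Interferon response genes went the other way in monocyte-like cells. They were lower in 24 of 28 members, with a median of -0.51. IFI6, an interferon-induced membrane protein (chromosome 6, 84852782 to 84858072), was at 81.5 ± 27.2 against 227 ± 0.74 CPM, and the ubiquitin-like ISG15 (chromosome 6, 63363201 to 63364211) at 26.8 ± 11.12 against 58.6 ± 1.11. IFI44L and the nuclease ISG20 had log2 fold changes of -1.07 ± 0.26 and -1.63 ± 0.44. Camera called the list at an adjusted p of 5.63e-08, with an adjusted p of 0.679 with an estimated correlation, and by edgeR 1 member passed adjusted over the list alone, 0 over all genes. The scavenger receptor CD163 was lower (log2 fold change -0.74 ± 0.33), and MRC1 (1.23 ± 0.62) and SPP1 (-0.14 ± 0.35) overlapped between the groups. T cell markers were also lower in this class, in 9 of 9 (median -0.91, camera adjusted p = 0.000294, and adjusted p = 0.869 with an estimated correlation). Over all 11564 genes edgeR called 0, with 740 at unadjusted p under 0.05, against 49 by DESeq2.

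Macrophage-like cells showed higher osteoclast function genes, lower immediate early genes and lower interferon genes in the 1797 libraries. CTSK, the collagen-degrading protease of osteoclasts (chromosome 4, 98389459 to 98404969), was at 432 ± 73.8 against 224 ± 32.3 CPM. The integrin ITGB3 (chromosome 12, 16694466 to 16752228) was at 164 ± 3.05 against 97.1 ± 8.90, the proton pump subunit TCIRG1 at 123 ± 7.36 against 85.1 ± 0.99, and the gelatinase MMP9 at 252 ± 78.2 against 122 ± 33.1. KLF2, a transcription factor that restrains myeloid activation (chromosome 2, 61270733 to 61273037), was at 49.0 ± 3.80 against 108 ± 1.05, and the immediate early genes IER2 and FOS at 19.8 ± 3.25 against 43.1 ± 5.74 and 352 ± 29.9 against 570 ± 1.91. CXCL9, the interferon-gamma-induced chemokine that draws T cells (chromosome 8, 71665541 to 71670236), was at 1.91 ± 0.04 against 13.04 ± 5.74 CPM.

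Osteoclast function was higher in 15 of 16 members (median 0.41), and 10 had both 1797 libraries above both controls. Camera called the list at an adjusted p of 5.75e-05, with an adjusted p of 0.538 with an estimated correlation, and 5 members passed edgeR adjusted over the list alone. At Leiden resolution 0.5 and with another clustering seed, which both put the 205 osteoclast-like cells into the macrophage-like class, the camera adjusted p was 0.415 and 0.35 (lowest over all alternatives 3.78e-06), and MMP9 had a log2 fold change of -0.07 in each in place of 1.05. The list of dissociation and immediate early stress genes was lower in 27 of 30 (median -0.52, camera adjusted p = 4.56e-11, and adjusted p = 0.538 with an estimated correlation), with 13 at unadjusted p under 0.05 and 3 passing edgeR adjusted over the list alone. KLF2 had a log2 fold change of -1.14 ± 0.14 and NR4A2, an immediate early nuclear receptor, of -0.73 ± 0.18.

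In the same cells interferon response genes were lower in 26 of 30 (median -0.42, camera adjusted p = 1.23e-07, and adjusted p = 0.505 with an estimated correlation), with 3 passing edgeR adjusted over the list alone. Log2 fold changes were -2.76 ± 0.41 for CXCL9, -1.22 ± 0.22 for ISG15, -1.32 ± 0.27 for IFIT3 and -0.69 ± 0.17 for the RNA sensor IFIH1. Hypoxia and glycolysis genes were higher in 19 of 27 (median 0.38, camera adjusted p = 0.00376, and adjusted p = 0.538 with an estimated correlation), among them the glycolysis genes PFKP (0.60 ± 0.18), PGK1 (0.65 ± 0.23), PFKFB4 (0.57 ± 0.20) and PKM (0.47 ± 0.17), with 0 adjusted over the list alone by edgeR and 5 at unadjusted p under 0.05. Without control library 1 its camera adjusted p was 0.0507 (lowest 0.00068). TNF was at 2.69 ± 0.31 against 8.45 ± 4.25 CPM and CXCL8 at 508 ± 167 against 230 ± 119, while IL1B (0.22 ± 0.50), CCL2 (-0.30 ± 0.17), CD163 (-0.40 ± 0.56), MRC1 (0.37 ± 0.22) and SPP1 (0.43 ± 0.49) differed less. Markers of T cells were lower in this class in 9 of 9 (median -0.97), mainly against control library 1, with median levels of -0.328 and -0.264 against 0.764 and -0.127. Over all 12706 genes edgeR called 0 (every gene named here had an adjusted p of 0.527 or more), with 1130 at unadjusted p under 0.05, and DESeq2 called 92, among them KLF2, CXCL9, CTSK and ITGB3. The class joins a shallow cluster (757 and 515 cells of the 1797 libraries, 854 and 668 of the controls) and a deeper one (361 and 527 against 402 and 185).

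**Figure D2:**
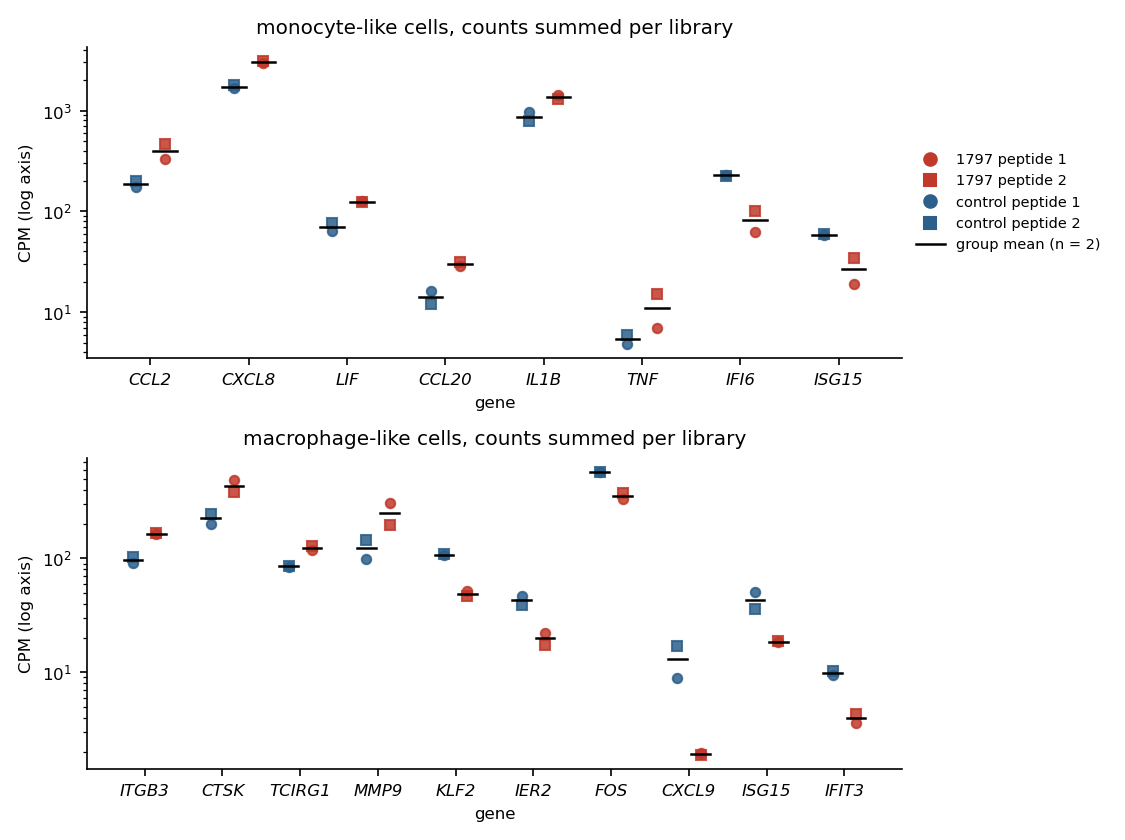
CPM of named genes (log axis) in counts summed per library over monocyte-like cells (top) and macrophage-like cells (bottom), with circles for library 1 and squares for library 2 of the 1797 (red) and control (blue) groups and black bars for group means (n = 2). In monocyte-like cells CCL2 has means of 399 and 187 and IFI6 of 81.5 and 227, and in macrophage-like cells CTSK has means of 432 and 224 and KLF2 of 49.0 and 108.

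Interferon response genes were measured in the other classes too. In neutrophil-like cells they were lower in 27 of 28 members, with a median of -0.85. IFI6 was at 21.9 ± 3.90 against 72.5 ± 15.7 CPM, and RSAD2, an antiviral enzyme, IFI44L and CMPK2 had log2 fold changes of -3.13 ± 0.84, -1.55 ± 0.45 and -2.65 ± 0.83. Camera called the list at an adjusted p of 3.34e-18, with an adjusted p of 0.939 with an estimated correlation and 0 members by edgeR adjusted over the list alone (6 at unadjusted p under 0.05). The call rested on control library 1, without which the camera adjusted p was 0.286 (lowest 7.26e-30). Median log2 levels of the list against the mean of the libraries were 0.94 there, -0.27 in control library 2 and -0.32 in both 1797 libraries. The class joins 4 clusters in unequal parts. A cluster led by interferon-induced genes held 253 of 2239 and 1302 of 5295 cells of this class in the 1797 libraries. In the controls it held 937 of 2031 and 2100 of 4185, a larger part in both. One with CXCL8 among its leading genes held 1857 and 3029 against 1027 and 732. Clusters with granule genes held 28 and 236 against 8 and 398, and 101 and 728 against 59 and 955. With all 4 libraries the camera call of the interferon list also held in the clusters with granule genes alone and in those without them alone. Chondrocyte markers were higher in this class in 7 of 7 (median 1.11), mainly in 1797 library 1, with median levels of 1.353 and 0.066 against -0.31 and -0.739. Of the fixed myeloid genes, CXCL8, IL1B, CCL2, MRC1 and SPP1 overlapped between groups, TNF was higher (0.47 ± 0.54) and CD163 lower (-0.64 ± 0.56), none past edgeR (adjusted p = 1). Over 11665 genes edgeR called 0, with 124 at unadjusted p under 0.05, and DESeq2 called 4 (HS3ST3A1, LOC100152327, LOC110257072 and TDRD9, named after their values were seen).

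Endothelial-like cells, which line vessels, had interferon genes lower in 24 of 29 (median -0.34), with IFI6 at 148 ± 22.4 against 312 ± 66.1 CPM and ISG15 at 232 ± 14.3 against 335 ± 8.54. Camera called the list at an adjusted p of 0.00247, with an adjusted p of 0.824 with an estimated correlation, and without 1797 library 1 its p was 0.417 (lowest 0.000183). NK or cytotoxic T-like cells had the same list higher, in 19 of 27 (median 0.21), with log2 fold changes of 1.02 ± 0.29 for IFIT3 and 0.90 ± 0.31 for RSAD2. There the camera adjusted p was 0.00298, with an adjusted p of 0.943 with an estimated correlation. Without 1797 library 2 and without control library 1 the NK list had camera adjusted p of 0.912 and 0.163 (lowest 1.47e-07). In both classes edgeR called 0 genes (481 and 391 at unadjusted p under 0.05) and 0 members adjusted over the list alone, and DESeq2 called 15 and 13.

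T cell-like cells had lower transcripts of cytotoxic effectors and of MHC class II presentation. All 14 tested cytotoxic genes were lower (median -0.52). The chemokine CCL5 was at 49.0 ± 8.56 against 104 ± 8.48 CPM (log2 fold change -1.09 ± 0.17) and GNLY at 2.02 ± 0.83 against 7.83 ± 2.07 (-1.95 ± 0.38). Camera called the list at an adjusted p of 1.13e-06, with an adjusted p of 0.556 with an estimated correlation, and CCL5 and GNLY were the 2 members past edgeR adjusted over the list alone. DESeq2 called both (adjusted p = 0.000146 and 0.0202). The level of GNLY in NK or cytotoxic T-like cells was 121.38 times that in the median class. That class had a smaller mean share in the 1797 libraries (6.82% against 12.2%), and free RNA from it was not tested for this list. MHC class II presentation genes, which present peptides to helper T cells, were lower in 10 of 13 (median -0.67, camera adjusted p = 4.72e-05, and adjusted p = 0.556 with an estimated correlation). SLA-DQA1 (-0.71 ± 0.17), SLA-DMB (-0.72 ± 0.23), SLA-DMA (-0.70 ± 0.22) and SLA-DRA (-0.70 ± 0.27) had similar fold changes, with 0 members adjusted over the list alone by edgeR and 5 at unadjusted p under 0.05. Macrophage or monocyte markers (12 of 12, median -0.76, camera adjusted p = 4.1e-06, and adjusted p = 0.291 with an estimated correlation) and B cell markers (8 of 8, median -0.49) were lower in these cells as well, and chondrocyte markers were higher (7 of 7, median 0.79). Cytosolic ribosomal protein genes were lower in 72 of 72 in T cell-like cells (median -0.19, camera adjusted p = 2.71e-17, and adjusted p = 0.556 with an estimated correlation) and in 72 of 72 in B cell-like cells (median -0.18, camera adjusted p = 1.31e-09, and adjusted p = 0.894 with an estimated correlation), where it was 0.14 without control library 1 (lowest 3.79e-18). In T, B and dendritic cell-like cells edgeR called 0 genes, with 630, 892 and 609 at unadjusted p under 0.05, and DESeq2 called 43, 54 and 20.

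Stromal or osteoblast-like cells are the class that makes bone, and they were tested although 1797 library 2 held 45 of them, against 336, 118 and 221 in the other libraries. RUNX2, the master regulator of osteoblasts, was at 2639 ± 369 against 2807 ± 309 CPM (log2 fold change -0.09 ± 0.28). ALPL, the phosphatase of mineralisation, was lower at 98.0 ± 42.9 against 226 ± 122, and SPP1, which encodes osteopontin, was higher at 4478 ± 586 against 2540 ± 844. The osteoblast regulator SP7 (-0.66 ± 0.37) and collagen gene COL1A1 (-0.96 ± 0.47) were lower in both 1797 libraries, and IBSP (-0.28 ± 0.30) and POSTN (-0.02 ± 0.35) overlapped. BGLAP, which encodes osteocalcin, had a log2 fold change of -3.66 ± 1.45 that rested on control library 1 (2243 CPM, against 53.3 in control library 2), and without it the value was 0.76.

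Bone matrix and mineralization genes were lower in 20 of 25 in this class (median -0.54, camera adjusted p = 0.0212, and adjusted p = 0.61 with an estimated correlation). The call was lost without 1797 library 1 (0.121), without 1797 library 2 (0.123), without the low-count filter (0.0598) and without control library 1, where the direction turned (0.273, lowest 2.17e-09). Inflammatory cytokines and NF-kB targets were higher in 18 of 20 (median 0.58, camera adjusted p = 3.75e-05, and adjusted p = 0.52 with an estimated correlation), with log2 fold changes of 2.21 ± 0.74 for the inflammasome gene NLRP3, 0.95 ± 0.35 for the chemokine CXCL2, 0.79 ± 0.32 for the dismutase SOD2 and 2.24 ± 0.98 for the cytokine IL6. Without 1797 library 2 that camera adjusted p was 0.0907 (lowest 2.7e-06). In that library, with 45 cells, the list's median level was 0.708 and that of macrophage or monocyte markers 0.854, against -0.08 and -0.405 in 1797 library 1, -0.451 and -0.483 in control library 1 and -0.092 and 0.085 in control library 2. For both lists 0 members passed edgeR adjusted over the list alone. Of 12572 genes edgeR called 0, with 296 at unadjusted p under 0.05, and DESeq2 called 3, the cartilage collagen COL2A1, SLA-1 and TFEC, which were named after their values were seen.

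Differences between classes were tested with interaction terms, which were not among the tests fixed before the data were examined. Stress and immediate early genes differed between monocyte-like and macrophage-like cells, with a median over genes of the difference in log2 fold change of 0.66 (camera adjusted p = 2.81e-14, and adjusted p = 0.261 with an estimated correlation), and inflammatory genes with one of 0.29 (camera adjusted p = 6.44e-05, and adjusted p = 0.659 with an estimated correlation). The interferon list did not differ between these classes by the same test (camera adjusted p = 0.373). It differed between NK or cytotoxic T-like and monocyte-like cells by 0.85 (camera adjusted p = 1.52e-16, and adjusted p = 0.416 with an estimated correlation). For single genes edgeR called 0 of 13083 between monocyte-like and macrophage-like cells, with 1260 at unadjusted p under 0.05, and DESeq2 was not run on these terms.

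**Figure D3:**
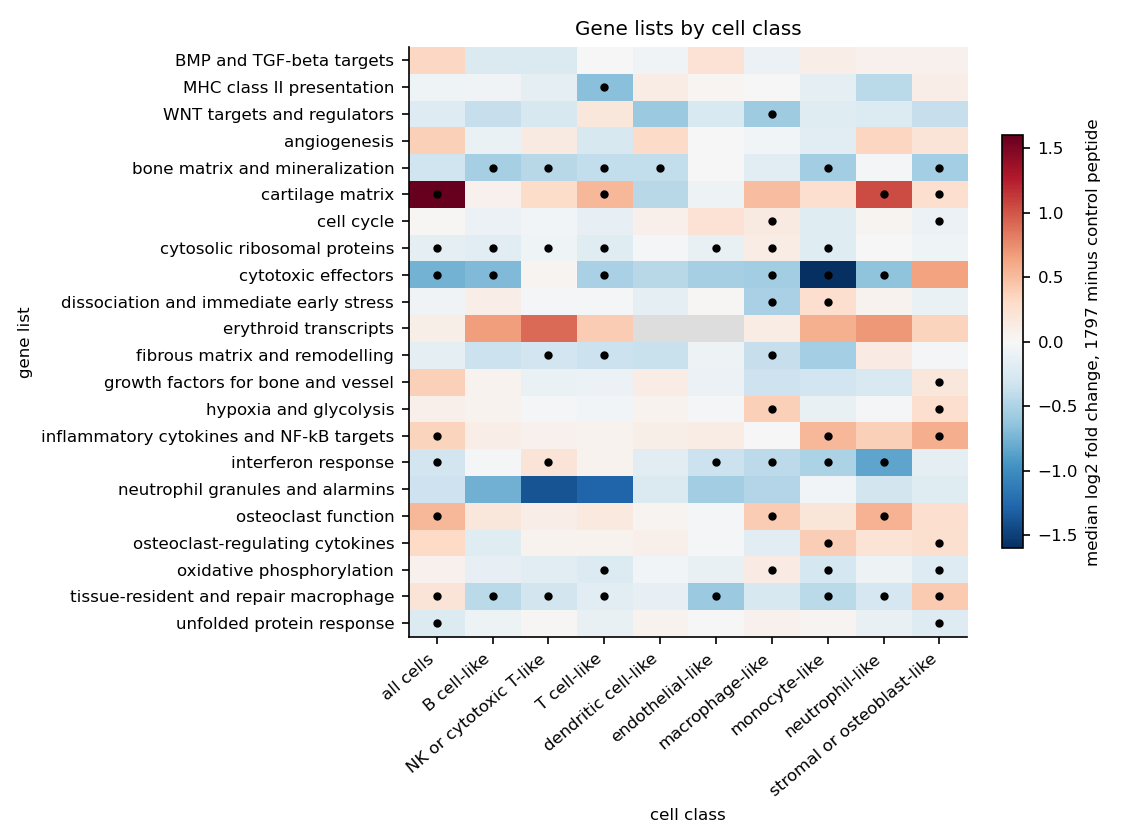
Median log2 fold change (1797 minus control, colour scale) of 22 gene lists in the sum of all cells, 8 tested classes and the stromal or osteoblast-like class, with black dots where camera with a preset correlation gave an adjusted p under 0.05 and grey where fewer than 5 members were tested. Cartilage matrix is at 1.62 in all cells, interferon response at -0.85 in neutrophil-like cells and inflammatory cytokines at 0.53 in monocyte-like cells, and 0 of the calls held with an estimated correlation.

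A small group of genes differed in the same direction in many classes, and they were chosen after their values were seen, as genes at unadjusted p under 0.01 the same way in at least 4 of the 8 classes. There were 17 of them. Both other ways to split the 4 libraries into pairs gave more, 43 and 30. The class I MHC gene SLA-1 (chromosome 7, 22824137 to 22920154), which presents peptides to cytotoxic T cells, was higher in 8 of 8 classes with a median log2 fold change of 1.48 and a range of 0.94 to 1.6. LOC100513601 (chromosome 7, 22888616 to 22920154) overlaps it, carries the same name as a synonym and was lower in 8 of 8 (median -1.20). The values of both are uncertain, since how reads were divided between the overlapping loci was not analysed here. ERAP2, which trims peptides for class I MHC (chromosome 2, 103510425 to 103563482), was lower in 8 of 8 (median -1.13). So was MT-2B, a metal-binding metallothionein (chromosome 6, 18645125 to 18646034), with a median of -1.99, and the neighbouring LOC102166944 (chromosome 6, 18660665 to 18662000) in 6 of 6 (median -2.93). LOC100525692 (chromosome 3, 64878759 to 64879669) was higher in 8 of 8 with log2 fold changes between 1.71 and 1.96. SLX4IP (median 1.02), the cell cycle gene CCNG2 (0.77) and TTC17 (0.75) were higher in 8 of 8, and IFI6 (-1.13) and GNLY (-1.43) lower in 8 of 8. By edgeR none passed over all genes in its class, and DESeq2 called SLA-1 in B, T, NK, dendritic, endothelial, macrophage and monocyte-like cells.

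**Figure D4:**
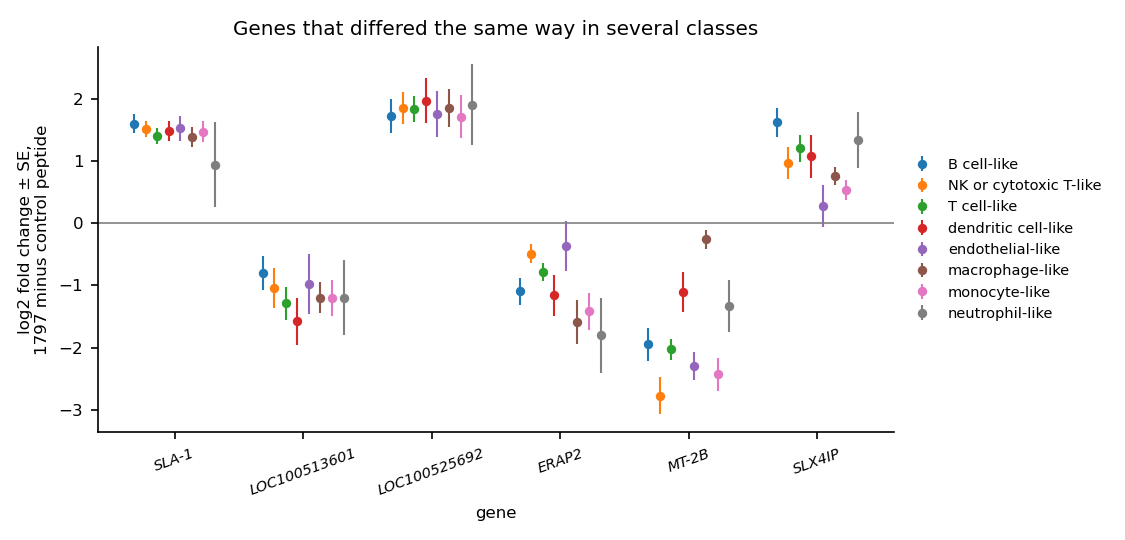
Log2 fold change ± SE (1797 minus control, y axis) of 6 genes (x axis) in each of the 8 tested classes (colours). SLA-1 and LOC100525692 lie above 0 in 8 of 8 classes with medians of 1.48 and 1.84, and LOC100513601, ERAP2 and MT-2B below 0 in 8 of 8 with medians of -1.20, -1.13 and -1.99.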

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

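The comparisons between classes below, and the tests of explanations, were chosen after the results were seen. A total of 6 comparisons drew attention because both 1797 libraries lay above both control libraries in 1 class and below both in the other, in the median of a gene list that camera called with the preset correlation in both classes. The differences below are between the medians of 2 classes, and the p-values beside them are from interaction tests of the differences gene by gene.

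Genes of cytosolic ribosomal proteins had a higher median log2 fold change in macrophage-like cells than in NK or cytotoxic T-like cells (by 0.19), T cell-like cells (by 0.31) and endothelial-like cells (by 0.245). Interaction tests gave camera adjusted p of 7.97e-08, 1.14e-25 and 5e-06, and adjusted p of 0.655, 0.448 and 0.722 with an estimated correlation. Genes of oxidative phosphorylation, the respiratory chain, had a higher median log2 fold change in macrophage-like than in T cell-like (by 0.351) and monocyte-like cells (by 0.408). Their interaction tests gave camera adjusted p of 3.01e-07 and 1.17e-06, and adjusted p of 0.35 and 0.751 with an estimated correlation. For genes of dissociation and immediate early stress the median log2 fold change was higher in monocyte-like than in macrophage-like cells, by 0.794. The camera adjusted p of that interaction test was 2.81e-14, and 0.261 with an estimated correlation.

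The macrophage-like class held lower immediate early genes and higher osteoclast function genes in the 1797 libraries, the pattern weighed here. The pattern was present within the deeper of its 2 clusters alone, so a different mix of the clusters is not needed for it. Both medians there were 1.09 times as large as in the class. With a median of 23056 UMIs per cell against 859, the deeper cluster weighs most in the class sums. Similar medians were thus likely beforehand. Less stress of tissue digestion in this class alone stays open for the immediate early genes. Of the 7 other classes 0 had a stress median below -0.2, which does not exclude it. Osteoclast-like cells or their RNA within the class remain a candidate explanation for the osteoclast genes, since 88.9% of 18 other genes abundant in osteoclast-like cells (over 500 CPM there and at least 5-fold above macrophage-like cells) were also higher in macrophage-like cells, with a median of 0.341, against medians of 0.03, 0.069 and 0.12 for the same genes in T, B and NK-like cells. An effect of the 1797 peptide, with 2 libraries per group, stays open beside it.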

How the results depend on the processing

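The stromal or osteoblast-like class, the settings of the macrophage and neutrophil clusters, another clustering seed, and list tests with other size factors, a stricter cell filter or other Leiden resolutions were chosen after the data were seen. Fits that leave out 1 library keep a lone library in 1 group, which is assumed to vary like the others. The causes of the differences below were not tested unless stated. Of the 22 called gene lists described, 22 kept their direction and call with other size factors, with doublets kept and with the stricter cell filter, 21 without a filter on low counts, 15 of 17 at Leiden resolution 0.5, 17 of 17 at 2.0 and 16 of 17 with another clustering seed. Osteoclast function in macrophage-like cells was lost at 0.5 and with the other seed (camera adjusted p = 0.415 and 0.35), where the class then held the 205 osteoclast-like cells too, and the stress list in monocyte-like cells was lost at 0.5 (0.102). With an estimated correlation 0 list calls held, and 0 with fry, against 53 over the tested units and 10 in the stromal or osteoblast-like class, where the fit without the low-count filter called 6. With a library left out the calls numbered 72 to 81 over the tested units (81 without 1797 library 1) and 1 to 10 in the stromal or osteoblast-like class. The inflammatory list over all cells had a camera adjusted p between 3.56e-08 and 0.285 with a library left out, and the bone matrix list in stromal or osteoblast-like cells between 2.17e-09 and 0.273. The lists described that lost their call without 1 library numbered 5 for 1797 library 1, 4 for 1797 library 2, 7 for control library 1 and 1 for control library 2.

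The edgeR test called 0 genes in the sum of all cells and in each class, also with other size factors, doublets kept, the stricter cell filter, both other Leiden resolutions, the other seed and the added cluster settings. DESeq2 called 19 genes in the sum of all cells and 290 over the classes, namely 54 in B, 13 in NK or cytotoxic T, 43 in T, 20 in dendritic, 15 in endothelial, 92 in macrophage, 49 in monocyte and 4 in neutrophil-like cells, and 3 in stromal or osteoblast-like cells. Without the filter on low counts edgeR called 311 over the classes, with 10 in B, 11 in NK or cytotoxic T, 3 in T, 60 in dendritic, 172 in endothelial, 0 in macrophage, 35 in monocyte and 20 in neutrophil-like cells, and 3 in stromal or osteoblast-like cells. With a library left out edgeR called 0 in the sum of all cells and in macrophage-like cells and 20 to 151 over the classes, with 1 to 11 in B, 0 to 9 in NK or cytotoxic T, 0 to 27 in T, 0 to 90 in dendritic, 0 to 3 in endothelial, 0 to 2 in monocyte, 2 to 54 in neutrophil and 0 to 41 in stromal or osteoblast-like cells. Genes with few counts and lone libraries enter these fits. The replicate numbers were not established to pair the samples, since deviations of libraries with the same number correlated at -0.309 in the sum of all cells, 0.467 in neutrophil-like cells and between -0.092 and 0.059 in the other classes. With the replicate block edgeR called 6 genes over the classes, 4 in NK or cytotoxic T, 1 in monocyte and 1 in neutrophil-like cells, the 22 lists kept their call, and the log2 ratio of the stromal or osteoblast-like share was -0.424 and that of POSTN there 0.04.

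Of the 14 classes 0 differed in share under any alternative, and the values that changed sign were log2 ratios that had not been called. With a denominator without neutrophil and erythroid cells T cell-like cells had 0.052 and stromal or osteoblast-like cells -0.019. The stricter filter gave erythroid-like cells -0.214, and Leiden resolutions 0.5 and 2.0 gave macrophage-like cells -0.124 and -0.019. At resolution 0.5 a total of 12 classes had a counterpart and with the other seed 13, without osteoclast-like cells in either. With a library left out the log2 ratios ranged from -0.22 to 0.524 for B, -0.368 to 0.272 for T, -1.535 to 1.763 for endothelial, -0.179 to 2.707 for erythroid, -0.185 to 0.222 for macrophage, -0.062 to 0.438 for monocyte, -0.515 to 0.911 for neutrophil, -1.963 to 3.384 for pericyte or smooth muscle and -2.009 to 0.949 for stromal or osteoblast-like cells. Among the 82 values of named genes, MMP9 in macrophage-like cells was -0.07 at Leiden resolution 0.5 and -0.07 with the other seed, and 82 kept their sign with other size factors, with doublets kept and with the stricter filter. With a library left out, log2 fold changes that changed sign ranged in stromal or osteoblast-like cells from -0.25 to 0.07 for RUNX2, -4.64 to 0.76 for BGLAP and -0.39 to 0.49 for POSTN. In macrophage-like cells they ranged from -0.37 to 1.17 for IL1B, -1.56 to 0.24 for CD163 and -0.12 to 1.31 for SPP1, and in monocyte-like cells from -0.03 to 1.94 for MRC1 and -0.58 to 0.51 for SPP1. In neutrophil-like cells the ranges were -0.17 to 1.90 for IL1B, -0.05 to 1.51 for CXCL8, -0.99 to 0.39 for MRC1 and -0.30 to 1.35 for SPP1. Shares of small classes rest on few cells, such as 2 and 5 chondrocyte-like cells in the control libraries.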

Other observations

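The tests in this part were chosen after the results were seen, as were the genes named from the DESeq2 calls. In simulated data with 200 changed genes per run, many of the calls that DESeq2 made and edgeR did not were false. Their share was 34.3%, 40.9% and 46.7% in the monocyte, macrophage and T cell fits, and 52.9% in the sum of all cells. These shares depend on how many genes were changed, which is not known for the real libraries. They are thus not the false share of the genes named here, which may be higher. Outside neutrophil-like cells DESeq2 called 286 genes over the tested classes for the real groups, and 273 and 207 for the other splits. By edgeR 0 of the genes named here were called.

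Macrophage-like cells of the 1797 libraries held less CCL24, a chemokine for eosinophils (5.71 and 4.46 against 41.57 and 20.58 CPM, DESeq2 log2 fold change -2.63, adjusted p = 6.7e-06), and less IGF1, a growth factor for bone and muscle (26.42 and 21.37 against 60.59 and 75.69 CPM, -1.52, DESeq2 adjusted p = 1.79e-05). EGFR, the receptor of epidermal growth factor, was higher there (2.10, DESeq2 adjusted p = 0.00295) and the fibroblast growth factor receptor FGFR1 lower (-3.81, DESeq2 adjusted p = 0.00418). Dendritic cell-like cells held less of the arginine-degrading enzyme ARG1 (-1.73, DESeq2 adjusted p = 3.41e-05). In endothelial-like cells the alarmin IL33 (-3.90, DESeq2 adjusted p = 1.92e-05) and the scavenger receptor STAB2 (-2.85, DESeq2 adjusted p = 3.75e-06) were lower. The prostaglandin synthase PTGS2 was higher there (2.03, DESeq2 adjusted p = 0.0119). That class held 718 and 76 cells in the 1797 libraries and 164 and 250 in the controls. Its median depth was 2507 UMIs per cell in control library 1, 14383 in control library 2 and 8212 and 8128.5 in the 1797 libraries. PTGS2 was also higher in T cell-like cells (1.10, DESeq2 adjusted p = 0.000338), together with BMP6, a bone morphogenetic protein (1.05, adjusted p = 0.00119).

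Some metallothionein genes, which bind zinc and copper, were among the DESeq2 calls, and no list of such genes was tested. In monocyte-like cells MT-2B was at 262.56 and 323.76 against 1934.71 and 1231.46 CPM (DESeq2 log2 fold change -2.42, adjusted p = 1.65e-13) and MT1A at 0.19 and 1.51 against 18.1 and 13.16 (-3.99, adjusted p = 9.32e-07). The heat shock gene HSPA6 was lower in monocyte-like (-2.60) and macrophage-like cells (-1.95), with DESeq2 adjusted p of 9.44e-08 and 0.000341. In the sum of all cells MT3 and MT1D were lower (-3.09 and -3.56, DESeq2 adjusted p = 0.00198 and 0.0176), and the cartilage genes CYTL1 and UCMA were higher (5.46 and 3.92, DESeq2 adjusted p = 9.87e-06 and 0.00319). HS3ST3A1, a heparan sulfate sulfotransferase, was at 87.51 and 20.05 against 0.61 and 0.2 CPM in neutrophil-like cells (DESeq2 adjusted p = 1.47e-10).

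The cells of the unnamed clusters were counted but not tested. One with EPX and ALOX15, genes of eosinophils, among its leading genes held more cells in library 2 of both groups, with 38 and 207 in the 1797 libraries and 71 and 492 in the control libraries. Another had KIT, FCER1A, MS4A2 and GATA2, genes of mast cells and basophils, together with the T cell genes CD3E and LCK. It held fewer cells in both 1797 libraries, with 95 and 88 against 202 and 133. A cluster with the cell cycle genes TOP2A and MKI67 held 38 and 11 against 43 and 27.

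Inflammatory genes were higher in monocyte-like cells of the 1797 libraries. Free RNA from neutrophils as the cause for the whole list is argued against, since 8 of 22 members measured in both classes had a higher CPM in neutrophil-like cells of the 1797 libraries than in monocyte-like cells of the control libraries. IL1B, for example, had 45.7 against 872. For those 8, CCL5, CCL20, CXCL2, CXCL8, LIF, OSM, TNF and TNFAIP6, it cannot be told apart from a change within monocytes, as their median log2 fold change was 0.3 over T, B and NK-like cells and 0.75 in monocyte-like cells. CXCL8 among them had 0.969, 0.583 and 0.917 in T, B and NK-like cells against 0.811 in monocyte-like cells. For LIF the values were 0.462, 0.285 and 0.066 against 0.825. Stress of tissue digestion stays a candidate explanation, since the stress list was higher in the same cells, with a median of 0.272. In macrophage-like cells of the same libraries that list was lower, with a median of -0.52. Its call in monocyte-like cells was lost at Leiden resolution 0.5 (camera adjusted p = 0.102). An effect of the 1797 peptide stays open beside stress. The smallest camera adjusted p of the inflammatory list in the other splits was 0.65 against 1.87e-12, but 3 splits of 4 libraries are too few to decide.

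The 17 genes that differed the same way in many classes may in part reflect differences in genotype between the animals sampled. SLA-1 and the overlapping LOC100513601 had opposite signs in 8 of 8 classes, which is consistent with differences at the class I MHC locus between the animals, for these 2 loci alone. Free RNA from 1 cell type as the cause of the whole group is argued against, since 3 of 17 genes, LOC100152327, GNLY and ERAP2, had a level in their highest class at least 10 times that in the median class, and it stays open for those. It stays open for MT-2B too, which was highest in monocyte-like cells at 9.92 times the median class, just under that cut. Both other splits of the libraries gave more such genes, 43 and 30, than the 17 of the real split. The 3 splits are too few for a share under 0.05, and an effect of the peptide was not tested separately.

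Over the tested classes and the sum of all cells the real groups gave 53 list calls by camera with the preset correlation. Both other splits of the 4 libraries gave at least as many, and the higher of them gave 64. In the sum of all cells edgeR called 0 genes in the real split and 446 in the highest other. DESeq2 called 19 there in the real split and 654 and 1331 in the others. By these counts the real groups did not stand out. The 3 splits are too few for a share under 0.05. The split that joined 1797 library 1 with control library 1 called 1286 genes by DESeq2 over the tested classes, against 290 for the real groups and 212 for the remaining split, and 13 against 0 by edgeR. Of the 1286 genes 1013 were in neutrophil-like cells, whose 4 clusters were filled in unequal parts, and there the real groups gave 4. That points to a structure of the samples other than the peptide groups in this class. Over the other tested classes the same split called 273, the real groups 286 and the remaining split 207. Of 218 pairs of a list and a class, 69 had both 1797 libraries on 1 side of both controls in the list's median, where chance alone gives 33.3%.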
